A study of [Clostridium] symbiosum
Bacteroides thetaiotaomicron VPI-5482
Bacteroides ovatus ATCC 8483
Bacteroides caccae ATCC 43185
Collinsella aerofaciens ATCC 25986
Blautia hydrogenotrophica DSM 10507
Marvinbr and [Clostridium] symbiosum
Bacteroides thetaiotaomicron VPI-5482
Bacteroides ovatus ATCC 8483
Bacteroides caccae ATCC 43185
Collinsella aerofaciens ATCC 25986
Marvinbryantia formatexigens DSM 14469
Esche with 490 samples.

How the data were processed

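The data came from feces of gnotobiotic C57BL/6 mice colonised with 8, 9 or 10 human gut bacteria. The 454 DNA libraries were made by COPRO-Seq, shotgun sequencing of fecal DNA in which reads are assigned to the genomes of the community members. The 36 RNA libraries were made from total RNA depleted of ribosomal RNA. Per the labels' protocols, pellets were frozen, cells were broken by bead beating, RNA was treated with DNase and depleted with columns and oligonucleotides before reverse transcription, and libraries were sequenced on a Genome Analyzer. The aligner, its version and the genome builds are not given in the sources used here.

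The labels of the 9-species samples disagree with themselves. Their titles name Desulfovibrio piger as left out, whereas the species list in their descriptions includes D. piger and omits Blautia hydrogenotrophica. The deposited files of these samples listed D. piger in each library and had no entry for B. hydrogenotrophica, and the 8-species files had no entry for either species. The groups are therefore named by their number of species, and the 9-species community is taken to hold D. piger.

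Each deposited DNA file gives, per the file headers, the count of reads per genome, with reads that matched several genomes equally well left out. In these DNA files, reads that matched a single place made up a count, and tied reads amounted to between 3.07% and 7.24% of mapped reads. Each deposited RNA file gives an expected count per coding sequence, per the file headers, in which tied reads were shared out as fractions to 1 decimal and intergenic reads were listed apart. Between 6.1% and 10.6% of the RNA values in a library were not whole numbers, and the expected counts were rounded to whole numbers before any count test. The test design had been written for whole counts, and the same edgeR test was kept for the rounded expected counts. Reads of near-identical copies of a gene, including copies in related genomes, were split between them by the authors' sharing of ties, so values of such genes are uncertain. Intergenic reads were left out of library sizes. They made up between 4.83% and 43.0% of mapped RNA reads.

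DNA libraries held between 282 and 11024104 assigned reads (median 604081). The lowest belonged to mouse 7 at day 14 of period 4 of the 13-mouse experiment, and the next lowest held 42946. Between 34.3% and 96.3% of the DNA reads were mapped (median 89.2%). RNA libraries held between 683366 and 6853955 reads in coding sequences (median 2968152). The number of coding sequences listed ranged from 3001 to 34184 per RNA library (median 24683), and 39416 were listed in 1 or more libraries. The 10 highest coding sequences took between 20.5% and 60.2% of a library's RNA reads. Intervals given for single libraries are 95% Wilson intervals. They cover counting error only, since reads of amplified libraries are not independent molecules. No libraries held identical values.

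Species were assigned to the genome names and to the locus prefixes of the coding sequences by name. The assignment was checked against the data, which matched it for some species only. Over the 36 pairs of RNA and DNA, the RNA share of a species correlated best with its own DNA share among the 10 for 5 species. The own species ranked 2 for B. caccae, 3 for E. rectale and B. thetaiotaomicron, and 4 for C. symbiosum and B. hydrogenotrophica (r from 0.0194 to 0.258 for these 5). The files pair each locus with the opening word of its product only, so genes are named by locus, by that word, or by a symbol written beside the locus in the gene lists.

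Shares of DNA reads were computed as log2 of (count + 1)/(total + 10), and days 4 and later were averaged to 1 value per mouse and period. The 13-mouse experiment (periods 2 to 4) and the 8-mouse experiment (periods 1 to 3, refined diets; periods 9 to 19, pureed foods) were fitted apart. For refined diets, the F statistic across diet codes was tested per species by 100000 permutations of diets within each period, one-sided by construction, with Benjamini-Hochberg adjustment over 10 species. For pureed foods, a linear model of the log2 share on the concentrations of 8 ingredients and the period was tested in the same way. The exception was periods 9 and 11, which were permuted together by mouse number, for this test and for the slopes. Each slope came from a separate fit of 1 ingredient and the period, without the other ingredients. Slopes were tested two-sided over 80 pairs of ingredient and species. In the 8- and 9-species communities, diets and communities were compared by exact two-sided permutation tests of 4900 arrangements (70 for D. piger, which only the 9-species community holds). RNA and DNA shares of the same mouse and period, and Bray-Curtis distances between days, were compared by two-sided sign-flip permutation tests with 100000 resamples. The smallest p these tests can give is 1e-05.

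RNA counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors and filterByExpr) in R 4.3.3, each species with its own library sizes, so that expression is relative to the RNA of the same species. Libraries with under 5000 reads of a species were left out for that species, and a species was tested with at least 20 libraries in the 13-mouse experiment or 8 in the 8-mouse experiment. This left 9 species, without Eubacterium rectale. Adjusted p-values are Benjamini-Hochberg values over all tested genes of all species, with a threshold of 0.05. Gene lists were tested with camera (limma 3.58.1) with a preset and with an estimated correlation, or, across diets, with Fisher's exact test. The 17 fixed lists covered O-glycan, alpha-mannan, fructan, glycosaminoglycan, pectin and starch loci of Bacteroides thetaiotaomicron, and stress, amino acid, respiration, fatty acid, sugar, ribosomal and sulfate genes of Escherichia coli. Of the 10 keyword lists, those for glycoside hydrolases, peptidases, flagella and hydrogenases had enough matching product words to be tested, which made 24 lists per comparison.

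Genes named in the text follow a fixed rule. Across diets, these are per species the 4 genes with the smallest p past the threshold and up to 4 members per list past it. Per contrast, these are the 10 higher and 10 lower genes with the largest change past the threshold whose libraries do not overlap, and up to 4 members of each list by p. All 10 species and up to 15 ingredient pairs past the threshold are named. The lists, tests, alternatives and this rule were chosen before the data were examined, except where the text says otherwise.

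The script for genes was tested on simulated data made from the real libraries. For TD.09053 against TD.09058 it recovered 1% of genes changed 4-fold and 4% of those changed 8-fold among 20233 genes. Across the diets of the 13 mice it recovered 1% and 10.1% among 20233 genes, and across those of the 8 mice 3.1% and 8.3% among 22562 genes. Unchanged genes called were 0, 2 and 6. Unchanged genes were simulated from 1 mean level per gene, so the many zeros of a library that lists few genes were not reproduced. These counts therefore do not cover false calls that such a library can bring. Without the 2 libraries that listed under 10000 genes, the shares recovered at 8-fold were 18%, 27% and 9.6%.

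Alternatives tried were the centred log ratio, the last day or all days, a pseudocount of 10 reads, the mouse number as a block, each mouse-period or library left out in turn, DESeq2 1.42.0, DESeq2's size factors, no filter on low counts, library sizes over all species, period or sequencing run as a covariate, and, chosen after seeing the data, fits without libraries of few reads or few genes, without features over 5% of their species, and with period 4 alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest. The labels do not state that replicates are separate animals, nor that a mouse number is the same animal in every period, so the p-values measure the spread between these samples. Shares are shares of assigned reads, not of cells.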

Results

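The series asked how the composition and gene expression of a defined human gut community in gnotobiotic mice respond to diet. The community held E. rectale, Bacteroides caccae, Bacteroides ovatus, B. thetaiotaomicron, Clostridium symbiosum, Collinsella aerofaciens, B. hydrogenotrophica, Marvinbryantia formatexigens, E. coli and D. piger. In the first experiment, 13 mice were fed 11 refined diets (codes TD.09049 to TD.09059) over 3 periods, which gave 39 mouse-periods with fecal DNA and 26 RNA libraries from periods 3 and 4. In another, 8 mice were fed 9 refined diets over 3 periods (24 mouse-periods with DNA, 10 RNA libraries from periods 1 and 2) and later mixtures of 8 pureed foods (48 mouse-periods with DNA). A further 16 DNA samples came from mice with 8 or 9 of the species on TD.09055 or TD.09057 (4 per group). The labels do not give the composition of the refined diets, so these are compared as codes only. They also do not say that a mouse number is the same animal in every period, and each mouse-period counts as 1 sample.

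Across the 11 refined diets of the 13 mice, with each mouse-period taken as a sample of its own, 7 of 10 species differed in their share of DNA reads. With the mouse number as a block in place of the period, 1 of these 7 passed (M. formatexigens, permutation adjusted p = 0.0233). In the 13 mice, each adjusted p beside a fold difference of DNA shares comes from the test across all 11 diets. The highest and lowest diets were picked from the same data, and the difference between them was not tested. E. rectale, a butyrate-producing Firmicute, was highest on TD.09052 (0.815% ± 0.166, SD, n = 3) and 4.36-fold lower on TD.09054 (0.196% ± 0.0754, n = 3; permutation test, adjusted p = 5e-05). M. formatexigens, an acetogen, ranged from 14.3% ± 5.82 on TD.09049 to 3.76% ± 1.00 on TD.09057 (n = 3 each; 3.71-fold; permutation adjusted p = 5e-05). D. piger, a sulfate reducer, ranged from 9.15% ± 11.5 on TD.09055 to 0.917% ± 0.335 on TD.09051 (n = 3 each; 5.85-fold between means of log2 shares; permutation adjusted p = 0.000433). The high mean on TD.09055 rests on 1 mouse-period, mouse 2 of period 2 (22.4%, 1 day), against 1.92% and 3.15% in the others. Without it the test across diets still passed (permutation adjusted p = 0.0007). For E. rectale and M. formatexigens the unadjusted p of 1e-05 is the smallest that the permutations can give.

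The other 4 species that differed moved by smaller factors. B. hydrogenotrophica, an acetogen that grows on hydrogen and carbon dioxide, was 2.01% ± 0.500 on TD.09051 and 1.14% ± 0.159 on TD.09055 (n = 3 each; 1.74-fold; permutation adjusted p = 0.0048). B. ovatus, a degrader of plant polysaccharides, was 18.1% ± 7.62 on TD.09058 (n = 5) and 8.96% ± 4.09 on TD.09055 (n = 3; 2.06-fold; permutation adjusted p = 0.00628). C. symbiosum was also highest on TD.09058 (5.97% ± 1.65, n = 5) and lowest on TD.09055 (3.09% ± 0.523, n = 3; 1.89-fold; permutation adjusted p = 0.00628). B. thetaiotaomicron was 31.4% ± 7.33 on TD.09056 and 19.0% ± 7.25 on TD.09049 (n = 3 each; 1.72-fold; permutation adjusted p = 0.0397). B. caccae (32.9% ± 4.28 over 39 mouse-periods), E. coli (6.29% ± 3.29) and C. aerofaciens (1.34% ± 0.787) did not pass (permutation adjusted p = 0.311, 0.0832 and 0.0909).

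The call for B. thetaiotaomicron was lost in 14 of 39 fits that left out a mouse-period: mice 5, 7, 9 and 10 of period 2, mice 3, 7, 8, 9 and 12 of period 3, and mice 1, 2, 4, 6 and 11 of period 4 (permutation adjusted p from 0.0504 to 0.0742, highest without mouse 10 of period 2). C. aerofaciens passed without mouse 4 of period 2 (0.0247) or mouse 1 of period 3 (0.0417), and E. coli without mouse 12 of period 2 (0.0368), mouse 4 of period 3 (0.0427), or mice 4 (0.0374) or 12 (0.0462) of period 4, in each case by permutation adjusted p. The calls for B. ovatus and B. thetaiotaomicron were lost on the last day of each mouse-period (permutation adjusted p = 0.130 and 0.168) and with all days averaged (0.0657 and 0.131). B. caccae (0.0122) and E. coli (0.015) passed under the centred log ratio, and C. aerofaciens (0.00115) and E. coli (0.0435) with all days averaged.

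**Figure D1:**
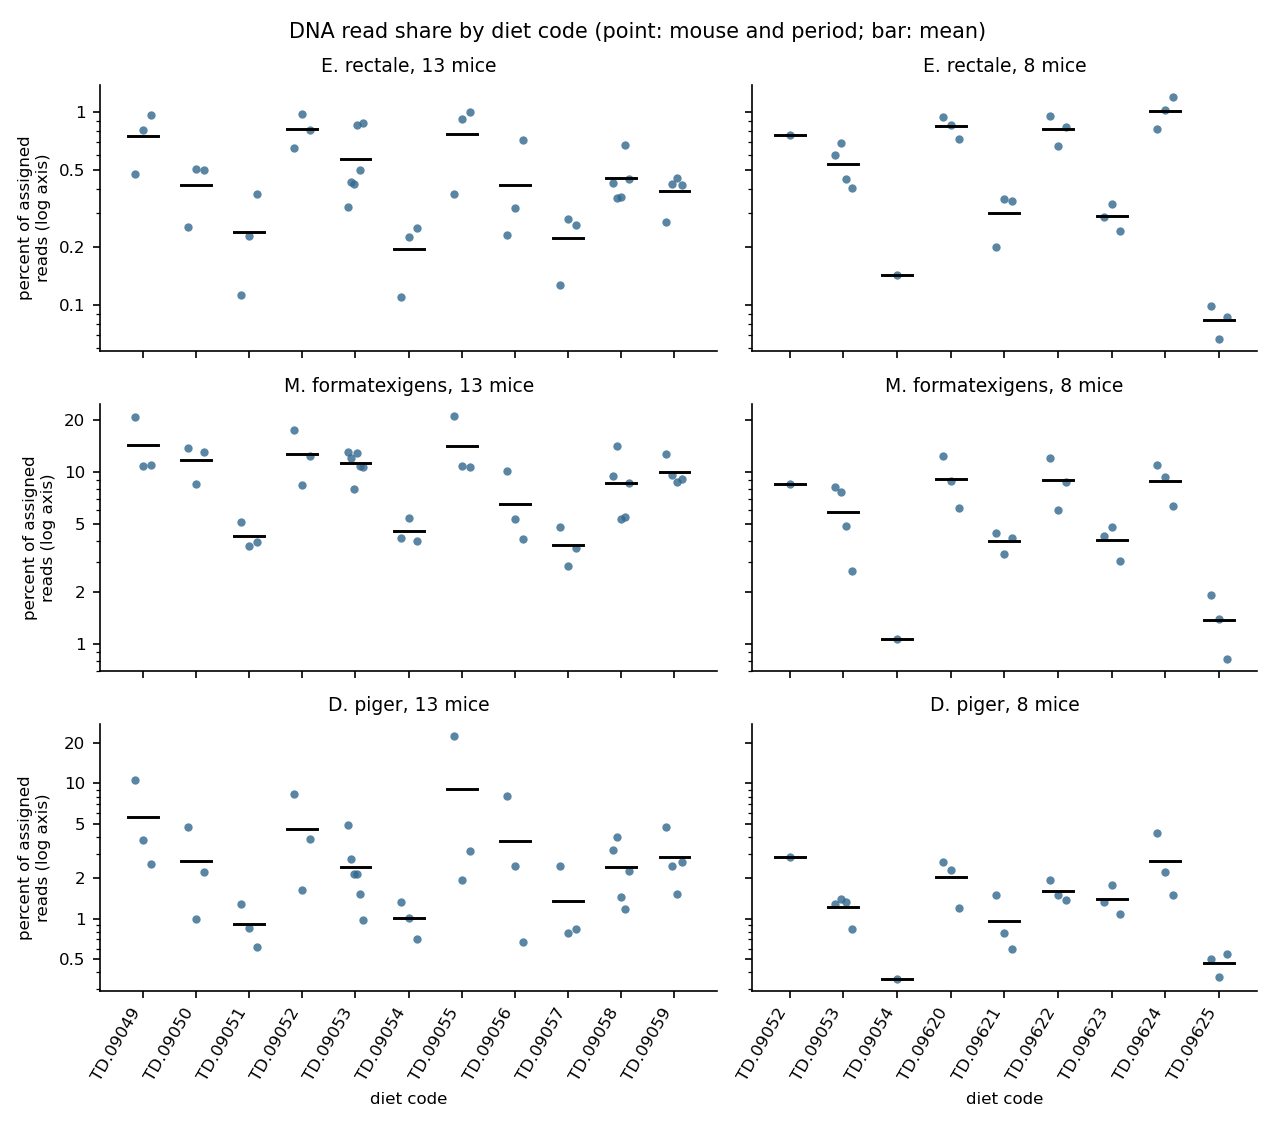
Percent of assigned DNA reads (log axis) of E. rectale, M. formatexigens and D. piger by diet code, with 1 point per mouse and period and a bar at the mean. E. rectale had a mean of 0.815% on TD.09052 and 0.196% on TD.09054 in the 13 mice, and of 1.02% on TD.09624 and 0.0835% on TD.09625 in the 8 mice.

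In the 8 mice, fed mostly other refined diets, 5 of 10 species differed, led by E. rectale, M. formatexigens and D. piger again. E. rectale was 1.02% ± 0.194 on TD.09624 and 12.2-fold lower on TD.09625 (0.0835% ± 0.0161, n = 3 each; permutation adjusted p = 0.0001). M. formatexigens was 9.14% ± 3.09 on TD.09620 and 1.39% ± 0.556 on TD.09625 (n = 3 each; 6.73-fold; permutation adjusted p = 0.0002). D. piger was 2.66% ± 1.46 on TD.09624 and 0.472% ± 0.0936 on TD.09625 (n = 3 each; 5.19-fold; permutation adjusted p = 0.0002). C. symbiosum was 4.63% ± 0.390 on TD.09623 and 3.07% ± 0.805 on TD.09624 (n = 3 each; 1.54-fold), and B. hydrogenotrophica was 2.47% ± 0.472 on TD.09621 and 1.35% ± 0.712 on TD.09624 (n = 3 each; 2.0-fold), both with a permutation adjusted p of 0.038. These are the extremes among diets with 3 or more mouse-periods, picked from the same data. Each adjusted p comes from the test across all diets of the 8 mice, and the differences between the extremes were not tested. With 1 mouse-period each, TD.09054 had less M. formatexigens (1.07%), D. piger (0.358%) and B. hydrogenotrophica (0.729%), and TD.09052 more D. piger (2.88%). B. caccae (36.6% ± 3.95), B. ovatus (13.6% ± 4.91), B. thetaiotaomicron (25.5% ± 5.24), C. aerofaciens (1.14% ± 0.528) and E. coli (7.71% ± 4.02) did not pass (n = 24; permutation adjusted p = 0.0868, 0.494, 0.724, 0.292 and 0.240).

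Those calls for C. symbiosum and B. hydrogenotrophica in the 8 mice were near the threshold (permutation adjusted p = 0.038), and many fits that left out 1 mouse-period lost them. Both were lost, which left 3 species, without mouse 4, 5 or 7 of period 1, mouse 1, 4 or 7 of period 2, or mouse 2, 4 or 8 of period 3. C. symbiosum was lost also without mouse 2 or 6 of period 1, mouse 6 or 8 of period 2, or mouse 3 or 6 of period 3 (15 of 24 fits, permutation adjusted p up to 0.0957, without mouse 8 of period 2). B. hydrogenotrophica was lost also without mouse 3 of period 1, or mouse 3 or 6 of period 2 (12 of 24 fits, up to 0.130, without mouse 8 of period 3). B. caccae passed without mouse 1 of period 1 (0.0435) or mouse 6 of period 2 (0.0402), and E. coli without mouse 6 of period 2 (0.0268). On the last day of each mouse-period both were lost too (0.345 and 0.395), and with all days averaged B. hydrogenotrophica was (0.117). B. caccae (0.00228), B. ovatus (0.00977) and E. coli (0.0415) passed under the centred log ratio, and B. caccae with all days averaged (0.00303). On TD.09053, fed in both experiments, E. rectale had 0.570% ± 0.237 in the 13 mice (n = 6) and 0.537% ± 0.132 in the 8 mice (n = 4), and M. formatexigens had 11.3% ± 1.89 and 5.85% ± 2.58, a difference that was not tested.

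With pureed foods, which asked which ingredient goes with which species, B. ovatus (38.9% ± 10.99) and B. thetaiotaomicron (37.4% ± 9.66) made up most of the DNA reads, and B. caccae made up 9.93% ± 5.43 (n = 48). E. rectale ranged from 0.0857% to 14.7%. The shares of all 10 species followed the ingredients (R squared from 0.530 for M. formatexigens to 0.821 for B. thetaiotaomicron; permutation adjusted p from 5e-05 to 0.0034). The mean shares of the others were 2.12% for C. symbiosum, 0.310% for C. aerofaciens, 1.34% for B. hydrogenotrophica, 2.49% for M. formatexigens, 2.29% for E. coli and 0.136% for D. piger.

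Of 80 pairs of ingredient and species, 13 passed (9 positive slopes, 4 negative). Slopes are log2 units of share per 100 g/kg, with standard errors, at n = 48 mouse-periods and a maximum of 666.7 g/kg. The standard errors count every mouse-period as a separate sample, whereas the permutations kept periods 9 and 11 of a mouse number together. Each comes from a fit of that ingredient and the period alone, so it is not adjusted for the other ingredients of the mixtures. Oat went with more B. ovatus (0.16 ± 0.03, permutation adjusted p = 0.0056), less B. thetaiotaomicron (-0.17 ± 0.02, 0.006) and less B. hydrogenotrophica (-0.31 ± 0.07, 0.0184). The ingredient labelled chick went with less E. rectale (-0.63 ± 0.17, 0.0123) and more C. symbiosum (0.15 ± 0.03, 0.00747), B. hydrogenotrophica (0.23 ± 0.07, 0.0292) and C. aerofaciens (0.25 ± 0.07, 0.0439). Beef went with less E. rectale (-0.65 ± 0.16, 0.0487) and more C. symbiosum (0.12 ± 0.03, 0.0123) and B. caccae (0.17 ± 0.05, 0.0439). Rice went with more D. piger (0.24 ± 0.06, 0.009), peach with more M. formatexigens (0.21 ± 0.06, 0.0353) and pea with more B. thetaiotaomicron (0.08 ± 0.02, 0.0481). No pair with apple or sweet potato passed. Peach with D. piger (-0.15, 0.0581) passed under the centred log ratio (0.0096), on the last day (0.0074), with all days averaged (0.0455) and with periods 9 and 11 averaged per mouse (0.0381). Apple with E. rectale (0.54, 0.0581) passed under the last 2 of these (0.0455 and 0.0441). Under the centred log ratio apple with M. formatexigens (0.0378), beef with C. aerofaciens (0.0348) and peach with C. symbiosum (0.0248, and 0.0439 on the last day) passed too, as did pea with C. aerofaciens with periods 9 and 11 averaged (0.0403). At an unadjusted permutation p under 0.05 there were 28 pairs.

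Of these 13 pairs, 6 were lost in some fits that left out a mouse-period, all of the pureed food periods. Without mouse 2 of period 13, the permutation adjusted p was 0.116 for chick and B. hydrogenotrophica (lost in 2 of 48 fits) and 0.131 for chick and C. aerofaciens (14 fits). Without mouse 3 of period 13 it was 0.201 for beef and B. caccae (11 fits) and 0.124 for beef and E. rectale (24 fits). It was 0.0794 for peach and M. formatexigens without mouse 3 of period 15 (3 fits) and 0.0991 for pea and B. thetaiotaomicron without mouse 7 of period 13 (20 fits). Without mouse 4 of period 15, 8 pairs passed. On the last day of each mouse-period, 4 of these 6 pairs were lost as well: chick with B. hydrogenotrophica (0.0932) and C. aerofaciens (0.0763), peach with M. formatexigens (0.0712) and pea with B. thetaiotaomicron (0.0561). Beef with B. caccae was lost with all days averaged (0.0579), and beef with B. caccae (0.063) and with E. rectale (0.0575) when periods 9 and 11 were averaged per mouse.

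**Figure D2:**
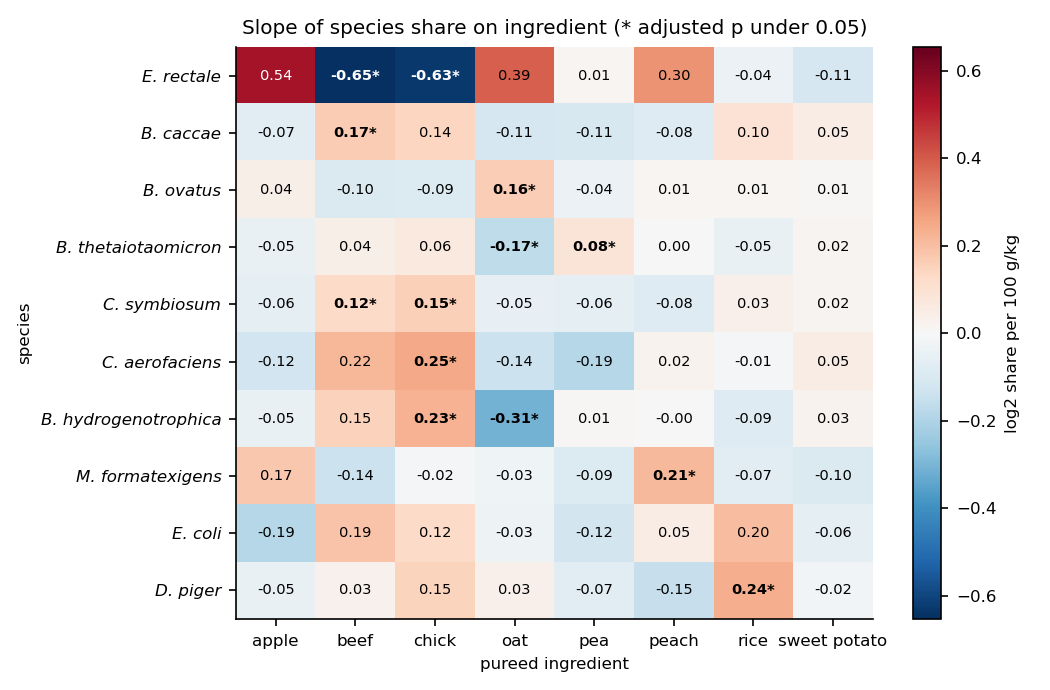
Slope of log2 DNA share on each pureed ingredient, per 100 g/kg, for the 10 species (48 mouse-periods), with an asterisk at an adjusted p under 0.05. E. rectale had the slopes -0.65 on beef and -0.63 on chick, and B. ovatus had 0.16 on oat.

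In the 8- and 9-species communities, which carry the diets TD.09055 and TD.09057 (written HF_LP and HF_HP in the sample titles, letters that the labels do not spell out), E. rectale was 22.7-fold lower on TD.09057. It made up 3.64% ± 1.16 on TD.09055 and 0.124% ± 0.0609 on TD.09057 with 8 species, and 2.60% ± 1.37 and 0.135% ± 0.0181 with 9 species (n = 4 each; log2 difference -4.50 ± 0.32, SE; exact permutation adjusted p = 0.00184). M. formatexigens was 6.63-fold lower (8.66% ± 2.70 and 1.13% ± 0.458 with 8 species, 6.11% ± 1.66 and 1.07% ± 0.238 with 9; log2 difference -2.73 ± 0.23; n = 4 each; exact permutation adjusted p = 0.00184). B. thetaiotaomicron was higher on TD.09057 (42.4% ± 4.19 and 50.3% ± 5.45 with 8 species, 37.01% ± 3.68 and 46.9% ± 3.16 with 9; log2 difference 0.30 ± 0.07; n = 4 each; exact permutation adjusted p = 0.00245). C. aerofaciens was lower (log2 difference -0.84 ± 0.29; exact permutation adjusted p = 0.0239), but not under the centred log ratio (0.042, adjusted p = 0.849), which also gave -3.62 for E. rectale, 1.18 for B. thetaiotaomicron and -1.85 for M. formatexigens.

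The other species of these communities did not pass between the diets. The log2 differences were 0.23 ± 0.09 for B. ovatus, 0.30 ± 0.15 for C. symbiosum and -0.63 ± 0.25 for D. piger, which was present in the 9-species community only (each with an exact permutation adjusted p of 0.0735). They were -0.06 ± 0.10 for B. caccae (0.564) and 0.17 ± 0.17 for E. coli (0.379). B. ovatus passed without replicate 2 of the 9-species TD.09055 group and C. symbiosum without replicate 3 of the 9-species TD.09057 group, which made 5 species in each case. Under the centred log ratio, B. caccae (0.82), B. ovatus (1.11), C. symbiosum (1.18) and E. coli (1.05) passed (exact permutation adjusted p = 0.000525 each), and D. piger had 0.19 (0.546). That scale sets each species against the mean log2 value of all species, which includes the large falls of E. rectale and M. formatexigens. The differences of the species in both communities all moved up by nearly the same amount (E. rectale from -4.50 to -3.62, B. caccae from -0.06 to 0.82). These calls therefore do not show a rise in share. In the 10-species mice, with 3 mouse-periods on each diet, E. rectale differed by -1.74, M. formatexigens by -1.88 and D. piger by -2.135, the largest, on the log2 scale (exact permutation p = 0.1, 0.1 and 0.2), where the smallest exact permutation p is 0.1. The D. piger value leans on 1 mouse-period on TD.09055, mouse 2 of period 2 with 22.4%, against 1.92% and 3.15% in the others on that diet.

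Between the communities, B. ovatus had a higher share with 9 species than with 8 (log2 difference 0.36 ± 0.09, SE; shares of reads without D. piger; exact permutation adjusted p = 0.0163), and none of the other 7 shared species passed (adjusted p from 0.276 to 0.976). This call was lost under the centred log ratio (0.37, adjusted p = 0.0882). No species passed the test of a diet effect that differs between communities (interaction, exact permutation adjusted p from 0.382 to 0.856; for B. ovatus the unadjusted p was 0.0478). The percent of reads mapped was 28.02 points higher on TD.09057 than on TD.09055 (exact permutation p = 0.00408, two-sided, n = 8 each), with means of 46.6% ± 18.7 and 78.8% ± 12.9 with 8 species and 49.9% ± 10.8 and 73.8% ± 14.1 with 9. The part of mapping in the diet differences of the species was not tested. Replicate 2 of the 8-species group on TD.09055, with 74.7% mapped, had 1.94% E. rectale. The others of that group (36.2% to 38.3% mapped) had 3.88% to 4.38%, and the highest share on TD.09057 was 0.211%.

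**Figure D3:**
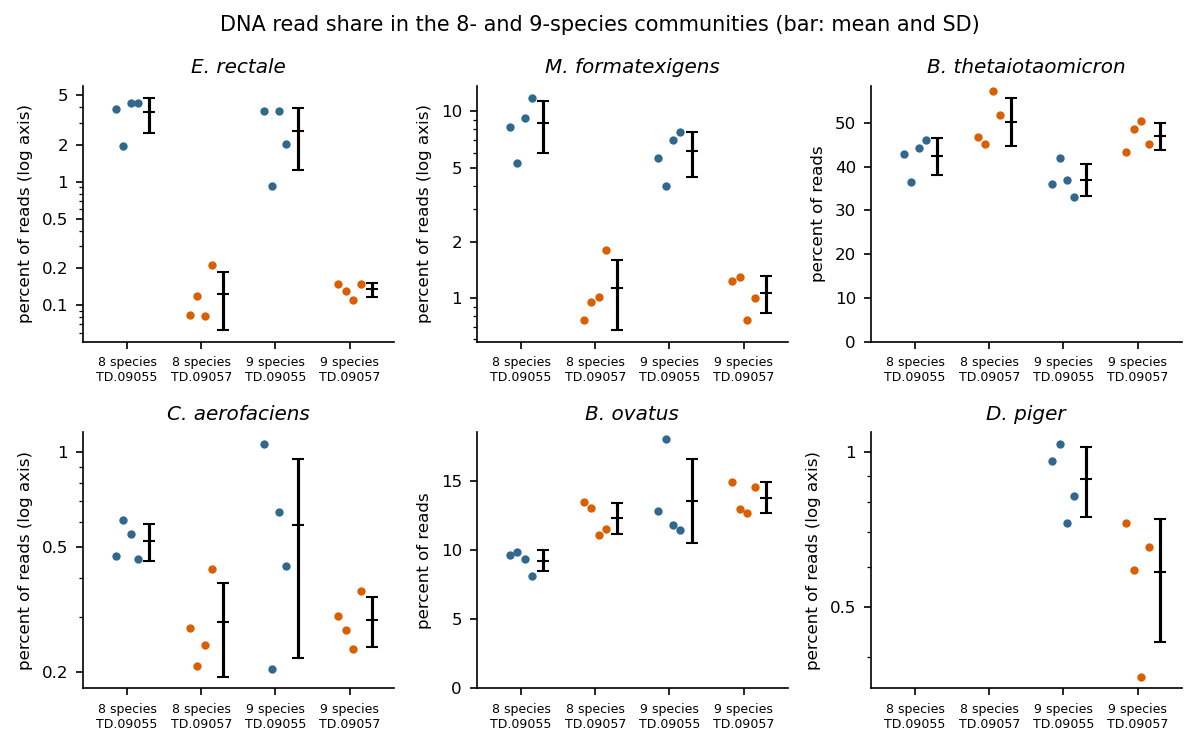
Percent of DNA reads of 6 species in the 8- and 9-species communities on TD.09055 and TD.09057, with 1 point per sample (n = 4) and a bar for the mean and SD. The highest E. rectale share on TD.09057 was 0.211%, below the lowest on TD.09055, 0.932%.

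RNA and DNA shares of the same mouse and period, compared over 36 pairs, differed for 8 of 10 species. B. thetaiotaomicron took 6.75% ± 2.21 of the RNA reads and 26.5% ± 5.30 of the DNA reads, 4.04-fold less, and its RNA share was the lower in every pair (0 of 36 higher). E. rectale was 7.16-fold lower in RNA (log2 ratio -2.84 ± 1.59, SD, higher in 3 of 36) and E. coli 3.08-fold lower (-1.62 ± 0.87, higher in 3 of 36). C. aerofaciens was 3.39-fold higher in RNA (1.76 ± 0.88, higher in 35 of 36), B. ovatus 1.92-fold (0.94 ± 0.48, 34 of 36), B. hydrogenotrophica 1.90-fold (0.92 ± 0.97, 29 of 36) and B. caccae 1.30-fold (0.37 ± 0.25, 32 of 36). Each of these 7 had a sign-flip permutation p of 1e-05, the smallest that the resamples can give (adjusted p = 1.43e-05). M. formatexigens was 1.65-fold lower (-0.72 ± 1.34, higher in 11 of 36; permutation adjusted p = 0.00354), while C. symbiosum (-0.01 ± 0.83, permutation adjusted p = 0.96) and D. piger (-0.22 ± 0.81, 0.120) did not pass. Under the centred log ratio M. formatexigens did not pass (-0.38, permutation adjusted p = 0.0525) and C. symbiosum did (0.34, 0.021). The log2 ratio was -1.40 in the 13 mice and -2.20 in the 8 mice for E. coli, and 1.56 and 2.28 for C. aerofaciens, differences that were not tested. RNA came from day 10 in the 13 mice and day 14 in the 8 mice, whereas DNA shares were averaged over days 4 and later. The RNA files include tied reads, whose listed number was between 32.6 and 81.6 per 100 mapped reads (median 66.4), and the DNA files leave them out (between 3.07% and 7.24%), and the part of this in the ratios was not tested. No species passed when RNA shares were compared across the diets of the 13 mice (smallest permutation p 0.304, smallest adjusted p 0.916).

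In the RNA of the 13 mice, the genes of fructan use in B. thetaiotaomicron had lower values on TD.09057 than on TD.09055. They made up 0.990% (95% Wilson interval 0.957 to 1.02) and 0.590% (0.558 to 0.624) of that species' RNA reads in the 2 libraries on TD.09055, and 0.0971% (0.0822 to 0.115) and 0.0585% (0.0479 to 0.0713) in the 2 on TD.09057. These intervals leave out the spread between libraries of the same diet. That spread was wide on TD.09051 (1.33% and 0.112%) and TD.09054 (0.796% and 0.109%), and small on others such as TD.09049 (0.266% and 0.202%). The median log2 difference over the 9 genes of the list was -3.24, with 8 of 9 lower, and 7 of 9 passed when adjusted over the list alone, against 0 of 9 adjusted over all genes (edgeR). BT1758 (-4.86 ± 1.45, SE), BT1765 (-3.36 ± 1.05), BT1762 (-4.99 ± 1.66) and BT1763 (-4.07 ± 1.38) had an edgeR adjusted p of 0.0134 over the list alone. Camera gave the list an adjusted p of 1.07e-14 with the preset correlation, and an adjusted p of 0.0729 with an estimated correlation, so that this call is lost. Without mouse 2 of period 3, mouse 6 of period 3 or mouse 1 of period 4, each on 1 of these diets, 0 of 9 genes passed over the list alone. The 2 libraries on TD.09057 shared a sequencing run, and those on TD.09055 came from 2 other runs. With the run as a covariate 2 of 9 passed over the list alone (median -3.11), and in period 4 alone, chosen after seeing the data, 0 of 9 did (median -3.30).

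Other B. thetaiotaomicron lists between these diets passed camera with the preset correlation only. The pectin list had a median of -1.59 (63 of 66 lower; adjusted p = 7.98e-12, and 0.768 as the adjusted p with an estimated correlation), but 1.28 with the sequencing run as a covariate, where the median of all genes moved to 1.26. The starch list had a median of -1.92 (7 of 8 lower; adjusted p = 0.00209, and 0.768 with an estimated correlation as the adjusted p), with BT3702 at -4.10 ± 1.52 (SE). The O-glycan list (median -0.65, adjusted p = 0.0363), and the E. coli lists of anaerobic respiration (-0.48, 0.0363) and ribosomal proteins (-0.45, 0.0123) each had an adjusted p of 0.991 with an estimated correlation. With library sizes over all species the median of the anaerobic respiration list was 0.05, and with the run as a covariate the O-glycan median was 1.85 and the ribosomal one 0.70. No member of these 5 lists passed adjusted over all genes or adjusted over the list alone (edgeR).

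Among the 3 contrasts of the diets with 3 or 4 RNA libraries, lists again passed with the preset correlation only. For TD.09053 against TD.09058, the B. thetaiotaomicron starch list had a median of -1.85 (7 of 8 lower; camera adjusted p = 0.0135) and the E. coli ribosomal proteins one of -0.52 (21 of 26 lower; 0.0371; 0.44 with the run as a covariate), and both had an adjusted p of 0.991 with an estimated correlation. For TD.09053 against TD.09059, the glycosaminoglycan list (1.21, 13 of 16 higher; 0.0176), the E. coli acid and general stress list (0.94, 9 of 11 higher; 0.0227) and the B. thetaiotaomicron glycoside hydrolases (0.65, 52 of 73 higher; 0.0227) passed, with an adjusted p of 0.999 each with an estimated correlation. The glutamate and GABA antiporter gene gadC of E. coli was higher on TD.09053 (4.19 ± 1.28, SE), the 1 of 11 stress genes that passed adjusted over the list alone (edgeR adjusted p = 0.0117), and 0 passed over all genes. For TD.09058 against TD.09059, the starch list had a median of 1.20 (7 of 8 higher; camera adjusted p = 0.0261, and an adjusted p of 0.983 with an estimated correlation). The lists not named here had a camera adjusted p over 0.05 in each of these 4 contrasts.

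No single gene passed in the 13 mice over the 20593 genes tested by edgeR. Across the 11 diets 0 genes passed (370 at an unadjusted p under 0.05, where chance gives 1030), and DESeq2 called 22. The contrasts gave 0 for TD.09057 against TD.09055 (416 unadjusted), TD.09053 against TD.09058 (390), TD.09053 against TD.09059 (431) and TD.09058 against TD.09059 (297), and DESeq2 called 1 gene in each. That gene was a glycogen gene of M. formatexigens (BRYFOR06574) for TD.09058 against TD.09059, a gene of C. aerofaciens with a hypothetical product (COLAER00354) for TD.09057 against TD.09055, and a hypothetical gene of B. caccae (BACCAC02643) for the other 2. The nearest gene across diets was a maltose-binding gene of M. formatexigens (BRYFOR05140, edgeR adjusted p = 0.154), chosen after its values were seen. It had 11180 CPM (reads scaled to a fixed total of its species' reads) on TD.09055 (392 and 21970 in the 2 libraries) and 269 on TD.09056, and was the 1 gene past without the library that lists under 10000 genes.

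Leaving out 1 RNA library of the 13 mice changed the count across diets from 0 to 69 without mouse 1 of period 3. In period 3 the counts were 10, 3, 9, 5, 5, 12 and 5 without mouse 2, 3, 5, 6, 8, 10 and 12, and in period 4 they were 6, 11, 7, 8, 15, 6, 3, 7 and 1 without mouse 1, 2, 3, 4, 5, 7, 8, 10 and 12. For TD.09053 against TD.09058, 1 gene passed without mouse 1 of period 3 or mouse 12 of period 4.

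**Figure D4:**
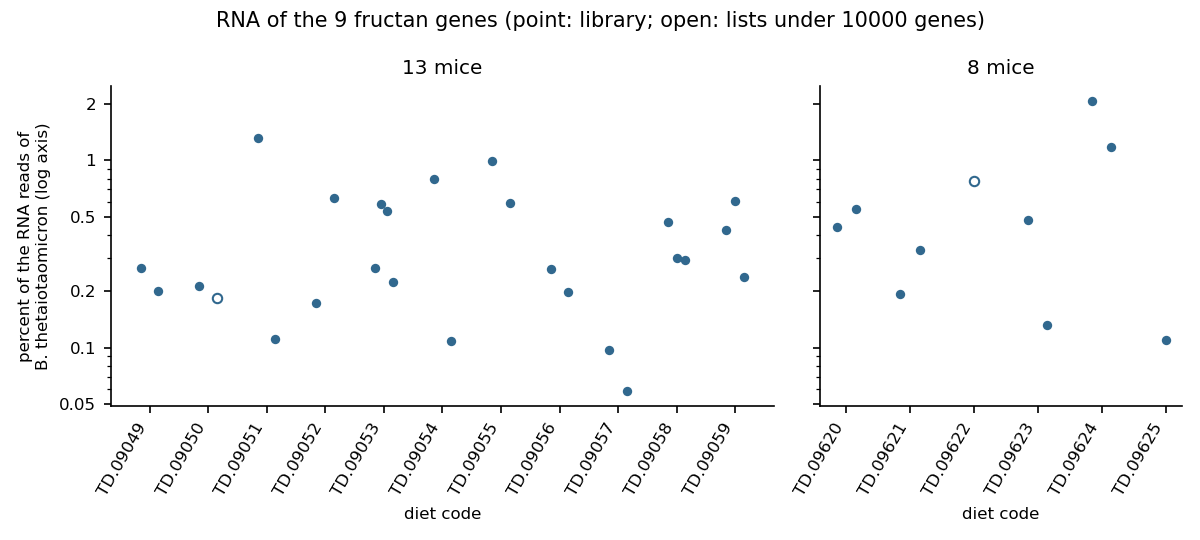
Percent of the RNA reads of B. thetaiotaomicron on the 9 fructan genes (log axis) by diet code, with 1 point per library and open points for libraries that list under 10000 genes. The 2 libraries on TD.09055 had 0.990% and 0.590%, the 2 on TD.09057 had 0.0971% and 0.0585%, and those on TD.09624 had 2.09% and 1.17%.

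In the RNA of the 8 mice, fructan genes of B. thetaiotaomicron varied across the diets in the fit with every library. Across the 11 diets of the 13 mice 0 of 9 passed (edgeR, 0 at an unadjusted p under 0.05), and their level gave a permutation p of 0.193 (adjusted 0.642), against 0.146 (0.215) in the 8 mice. BT1763 had 3264 CPM of its species' RNA reads on TD.09624 (n = 2, 1573 and 4954) and 96.3 on TD.09625 (n = 1), BT1759 (levanase) had 2748 and 133.4, and BT1757 (fructokinase) 1852 and 177.8. Of the 9 genes, 8 passed over all genes and 9 adjusted over the list alone (edgeR; Fisher's exact test adjusted p = 0.00023). A single library weighed on this fit. Mouse 8 of period 2, the only library on TD.09622, listed 3001 genes and had 20765 of the tested genes at 0. Without it, 0 fructan genes passed over all genes and 8 of 9 passed adjusted over the list alone (smallest edgeR adjusted p 0.00772).

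Across all genes of the 8 mice, 4072 of 23744 passed with every library (7015 at an unadjusted p under 0.05, where chance gives 1187). Of the 4072, 3754 were at 0 in the TD.09622 library, as were 20765 of all 23744 genes tested. Without that library 11 passed (785 unadjusted), all 11 among the 4072. Without mouse 4 of period 1 the count was 7738, and without mouse 1 of period 2 it was 10487, both libraries on TD.09623. Of the 11, 2 belonged to B. ovatus, 6 to C. symbiosum, 1 to B. hydrogenotrophica and 2 to M. formatexigens. The 2 of M. formatexigens, a methionine gene (BRYFOR07272; edgeR adjusted p = 0.0261 without that library) and a gene with a putative product (BRYFOR05086; 0.0339), had 7436 and 9346 CPM on TD.09625 (n = 1) and 159.8 and 111.9 on TD.09624 (n = 2), and the methionine gene had 6471 on TD.09621 (n = 2, 4322 and 8619).

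With every library of the 8 mice, the counts by species were 769 for B. caccae, 480 for B. ovatus, 596 for B. thetaiotaomicron, 452 for C. symbiosum, 231 for C. aerofaciens, 277 for B. hydrogenotrophica, 746 for M. formatexigens, 238 for E. coli and 283 for D. piger. A hexuronate gene of E. coli (b3093) had 8975 CPM on TD.09621 and between 1795 and 2539 on TD.09620, TD.09623, TD.09624 and TD.09625, but an edgeR adjusted p of 0.713 without the TD.09622 library. Of the 36 genes with the smallest p per species, 26 had no informative product word, 34 were at 0 in that library and 5 passed without it.

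Among the other lists in the 8 mice, the counts past the threshold over all genes and adjusted over the list alone (edgeR, every library) were 9 and 10 of 31 for O-glycan genes, 2 and 2 of 8 for starch, 1 and 0 of 34 for alpha-mannan, and 0 and 0 for glycosaminoglycan and pectin genes of B. thetaiotaomicron. For E. coli they were 4 and 4 of 5 for gluconate (gntT, gntU, eda and gntK; Fisher's exact test adjusted p = 0.00377), 4 and 4 of 22 for amino acid breakdown (tdcA, tdcB, tdcC and tnaB), 6 and 8 of 24 for anaerobic respiration, 2 and 2 of 6 for maltose uptake, 2 and 3 of 11 for mucosal sugars and 4 and 10 of 26 for ribosomal proteins. They were 0 and 0 for the E. coli lists of acid and general stress, amino acid synthesis, fatty acid breakdown, galactose and sulfate assimilation. Among keyword lists they were 12 and 12 of 75 for glycoside hydrolases of B. thetaiotaomicron and 12 and 16 of 31 for those of M. formatexigens. Peptidases had 7 and 7 of 12 in B. thetaiotaomicron (Fisher's exact test adjusted p = 0.0186), 2 and 3 of 14 in E. coli and 6 and 8 of 20 in M. formatexigens, E. coli hydrogenases had 2 and 3 of 14, and E. coli flagella had 0 and 0 of 10. In all, 83 members passed over all genes. Without the TD.09622 library 0 of them did, and of the 15 lists with a member past when adjusted over the list alone, only fructan remained.

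The time course asked how fast the community settled after a diet change. The mean Bray-Curtis distance to day 14 was 0.161 ± 0.0715 at day 1, 0.170 ± 0.0819 at day 2, 0.149 ± 0.0655 at day 4 and 0.153 ± 0.0750 at day 7. The difference between day 1 and day 7 was 0.0108 ± 0.0791 (SD, n = 36, positive in 20; sign-flip permutation p = 0.419, two-sided). C. aerofaciens moved most from day 1 to day 14 (absolute log2 change 1.20 ± 0.68, n = 47) and B. caccae least (0.29 ± 0.23). With the Aitchison distance, which gives rare species more weight, the difference was 0.367 ± 1.01 (positive in 23 of 36; permutation p = 0.0362).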

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

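The tests of exchanged labels, of few RNA molecules, of the library that lists few genes and of its ribosomal protein genes were chosen after the results were seen, and the tests of features with many reads and of depth before.

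In the RNA libraries of period 3 of the 13 mice, no match of the species shares to the DNA shares of the same mice was detected, which does not show that there is none. The mean correlation across the 10 species, each centred over the mice, was 0.0487 ± 0.483 (SD, 13 libraries, 7 positive; permutation p = 0.362, adjusted over 4 periods 0.362), against 0.259 ± 0.366 in period 4 (adjusted p = 0.0193), 0.314 in period 1 (0.158) and 0.570 in period 2 (0.0193) of the 8 mice, and the difference between periods was not tested. A small number of RNA molecules in some libraries is argued against, since libraries of period 3 that list more genes did not match their mouse better (Spearman's rho -0.478, one-sided permutation p = 0.950; Pearson's r -0.397, p = 0.911, and -0.168 without the 2 libraries farthest from the median; n = 13, 1 relation) and those with 20000 genes or more had a mean of -0.0255. Features over 5% of their species are argued against as well, since the mean without them was 0.0618. An exchange of labels within period 3 may account for it but cannot be told apart from chance matching: the best assignment of these libraries to the DNA of period 3 was reached by a share of 0.0016 of species-shuffled profiles, but that to the DNA of period 2 also by only 0.0047, and no biological explanation was tested.

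Most of the 4072 genes past the threshold across the diets of the 8 mice rested on the TD.09622 library (mouse 8 of period 2), which lists 3001 genes. A lower depth of that library is argued against, since it held 3736836 reads in coding sequences, above the median of 2968152 for RNA libraries. Thinned to 1600667 reads, the other 9 libraries each listed at least 13933 genes, while that library listed 2956. The explanation that 1 library with few listed genes makes the calls is consistent with the count of 11 without it, against 2872 or more without any other library. Expression changed by TD.09622 as the source of that library's zeros is argued against, since 0 of its 53067 E. coli reads fell on the 26 ribosomal protein genes, which growing cells need, where the lowest share among the other 9 libraries (0.471%) would give 250. Whether the diet changed some genes as well stays open and untested, since it has 1 library.

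Among 79 groups of 4 to 10 samples, 7 held a sample far from the others, and chance gives about 1 in 20 groups (3.95 here). B. caccae on TD.09058 was 25.5% in mouse 9 of period 4 of the 13 mice, against 33.03% to 35.99% in the other 4. E. rectale on TD.09059 was 0.269% in mouse 4 of period 2, against 0.421% to 0.453% in the other 3. On TD.09053, mouse 6 of period 3 of the 8 mice stood apart with B. thetaiotaomicron at 32.1% (others 25.5% to 26.3%) and C. aerofaciens at 0.285% (others 1.397% to 1.564%). Replicate 2 of the 8-species group on TD.09055 stood apart with E. rectale at 1.94% (95% Wilson interval 1.93 to 1.95; others 3.88% to 4.38%) and with 74.7% of reads mapped (others 36.2% to 38.3%). B. caccae was 34.96% (95% Wilson interval 34.92 to 35) in replicate 1 of the 9-species group on TD.09057, against 31.8% to 32.3% in the others.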

How the results depend on the processing

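The fits without low libraries or features, and with period 4 alone, were chosen after seeing the data; the others were planned. All 10 species passed with pureed foods under each alternative run. Between RNA and DNA 8 species differed under each, 7 of them the same under the centred log ratio, which lost M. formatexigens and added C. symbiosum. For the 13 mice, species past the threshold numbered 6 to 8 when a mouse-period was left out and 5 to 9 under other alternatives without a block. For the 8 mice the range was 3 to 6, with 8 under the centred log ratio and 3 on the last day. Ingredient pairs numbered 8 to 17 with a mouse-period left out. In the 8- and 9-species communities, species past between diets numbered 4 to 5 with a sample left out, 7 under the centred log ratio and 0 in the 10-species mice, where 3 mouse-periods per diet cannot reach the threshold. Species past between communities stayed at 1 with a sample left out and fell to 0 under the centred log ratio, of which the cause was not tested. Whether mouse numbers pair the samples was not tested. Deviations of the same number correlated with a mean of 0.0947, 0.160 and 0.108 in the 13 mice, the 8 mice and the pureed foods. The means for other pairs were lower, at -0.00691, -0.0354 and -0.0148. Of the same-number pairs, 20 of 39, 13 of 24 and 62 of 120 were over 0.1. If a number is 1 animal, its mouse-periods are not independent samples, which the tests blocked by period take them to be. With the mouse number as a replicate block in place of the period, 1 of the 7 species of the 13 mice passed (M. formatexigens, permutation adjusted p = 0.0233; E. rectale had 0.584 and D. piger 0.796). Differences between periods were not removed in these fits, so a call lost through them cannot be told apart from one lost through the mouse. In the 8 mice 4 species passed (E. rectale, M. formatexigens and D. piger of the 5, and B. caccae), and with pureed foods all 10. Of the 13 ingredient pairs 7 passed and 6 did not, among them oat with B. hydrogenotrophica (0.287, slope -0.145) and chick with C. symbiosum (0.0509), and 4 others did, apple with E. rectale (0.0137) and with E. coli (0.0372) among them, which made 11. With period as a block, genes past across diets were 0 in the 13 mice and 5298 in the 8 mice, and 0 in each contrast. The Aitchison distance turned the difference between day 1 and day 7 to 0.367, past the threshold; it is on another scale. For genes across diets in the 13 mice (0), the counts were 22 with DESeq2, 137 without a filter, 14 with library sizes over all species, 4 with the sequencing run, 1 and 8 without libraries under 10000 and 20000 genes, and 23 with period 4 alone, and 0 to 69 with a library left out. For TD.09057 against TD.09055 they were 1, 2, 1 and 4 with DESeq2, no filter, library sizes over all species and the sequencing run. For TD.09053 against TD.09058 they were 1 with DESeq2, 8 without a filter, and 1 without libraries under either 10000 or 20000 genes. For TD.09053 against TD.09059 they were 1 and 1, and for TD.09058 against TD.09059 1 and 2, with DESeq2 and without a filter. With a library left out the contrasts gave 0 to 1 for TD.09053 against TD.09058 and 0 for the other 3. In the 8 mice the 4072 genes became 11 and 1077 without libraries under 10000 and 20000 genes and 11 to 10487 with a library left out, against 4004 to 5597 with other tools, filters and scalings. Apart from fewer libraries or genes, the cause of these shifts was not tested. The fructan median between TD.09057 and TD.09055 stayed between -3.58 and -3.11 in all alternatives with all periods, and was -3.30 in period 4 alone, while 2 of 9 genes passed over the list alone with the run as a covariate. In simulated data at these library numbers, few genes changed 8-fold were recovered, more in the 13 mice without the libraries under 10000 genes, so a count of 0 does not exclude such changes; the cause was not tested.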

Other observations

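The code step test below was chosen after the result was seen, and the splits of the libraries were planned.

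The RNA and DNA shares of D. piger, a sulfate reducer, went together in the 8 mice. Pearson's r was 0.925 (permutation p = 0.00069, adjusted over 30 relations 0.0207; n = 10 libraries), Spearman's rho was 0.842 (permutation p = 0.0031), and r was 0.805 without the 2 libraries farthest from the median. It was the only one of the 30 relations of species and set of libraries past the threshold. Each period holds 5 of these libraries, too few for a value within a period. None of 26 lists passed a permutation test of its level, as a share of its species' RNA, across diets (smallest adjusted p 0.324 in the 13 mice and 0.067 in the 8 mice).

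In the 13 mice, E. rectale fell along runs of 3 consecutive diet codes (TD.09049 to TD.09051, TD.09052 to TD.09054 and TD.09055 to TD.09057), with means of 0.89, 0.10 and -0.99 on the log2 scale, relative to the mean of all 9 codes, at the first, middle and last code of a run. The place in the run accounted for 0.966 of the variance between these codes, more than any of the other 279 ways to part them into threes (share 0.00357, the smallest the 280 partings can give; adjusted over 10 species 0.0119). M. formatexigens (0.880) and D. piger (0.971) gave the same share, B. caccae, which went up along the runs, an adjusted value of 0.0268, and E. coli 0.993. A candidate explanation is that consecutive codes step 1 ingredient through 3 levels, which the labels do not say, and it was found and tested on the same data.

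For the contrasts TD.09053 against TD.09058, TD.09053 against TD.09059 and TD.09058 against TD.09059, edgeR called 0 genes in the real grouping of the RNA libraries of the 13 mice, so other splits of the libraries cannot test chance there. The highest counts of those splits were 1, 4 and 0.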
